A study of Mus musculus with 24 samples.

How the data were processed

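The series measured gene expression in 24 whole mammary glands of FVB mice with 1 Affymetrix mouse expression array per gland. Per the labels, 5 glands came from wild-type mice at 8 weeks of age, and 19 from transgenic mice that carry the SV40 large T antigen under the C3(1) promoter, at 8 weeks (5 glands), 12 weeks (5 glands), 16 weeks (5 glands) and 20 weeks (4 glands). RNA was isolated with Trizol and a column, and 100 ng of total RNA per gland was amplified with a Nugen protocol and labelled with biotin. Glands are named here by their age group and the gland number of their label. No gland number occurs in more than 1 group, so no samples were paired. The labels do not say whether each gland came from a different animal, and the tests treat the glands as independent. The labels give no batch, scan date or sex. The series title concerns silencing of Hoxa1 with small interfering RNA, but no array is labelled as treated. For every transgenic gland, including those at 8 weeks, the title and the tissue field speak of tumor where the source and the description speak of the whole gland; the text calls all samples glands.

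The deposited values are log2 expression values made by the authors with RMA, which corrects background, normalizes quantiles across arrays and summarises the probes of each probe set by median polish; the version is not stated. All 24 columns had medians near 5 and the log2 scale was checked on the value ranges. The values were used as deposited, without further normalization. The table holds 45101 probe sets, of which 64 are controls. In the annotation table of the array, 34958 probe sets named 1 gene symbol, 932 named several and 9211 named none. Of the probe sets naming 1 gene, 34754 were matched to a reference gene of the assembly GRCm38.p6 by Entrez number, and that reference was used only for names, chromosomes and the order of neighbouring genes. For each of 18194 genes the probe set with the highest mean over all arrays stood for the gene, and 9011 of these genes had more than 1 probe set. No filter on dim genes was applied. Hoxa1 and Kras had no probe set among those naming 1 gene, so neither was analysed here. For arrays, the number of glands per group limits the precision.

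The choices in this paragraph were made before the data were examined. Each comparison was tested with limma 3.58.1 in R 4.3.3, with a linear model of 1 mean per group fitted to all 24 arrays, moderated variances and two-sided tests. The p-values were adjusted by Benjamini and Hochberg over all 18194 genes, and a gene was said to rise, fall or change at an adjusted p under 0.05. The comparisons were transgenic against wild type at 8 weeks, 20 against 8 weeks within transgenic glands, the successive ages, and each later age against wild type at 8 weeks. An age slope per 4 weeks was fitted to the 19 transgenic arrays. For 27 gene lists with 551 entries, 508 of them measured, limma's camera compared each list with all other genes at a preset correlation between genes of 0.01, adjusted over 135 tests (27 lists in 5 comparisons). The same tests were run with an estimated correlation and with limma's rotation test fry, which asks whether the genes of a list move, on balance, one way. Counts of list members that passed the test are given over all genes and adjusted over the list alone. The lists came from textbook knowledge, and none was chosen on these samples.

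Genes were named by a rule. For transgenic against wild type at 8 weeks and for 20 against 8 weeks, these are the 10 largest rises and the 10 largest falls among changed genes whose groups did not overlap; for successive ages, 5 and 5. For each list, up to 4 members with the largest absolute change are named, or 2 where no member changed. Where fewer genes met the rule, all were named, and transcripts with clone names could be passed over.

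RNA quality was read from the 3-prime minus 5-prime difference of the Actb and Gapdh control probe sets and from the mean of 3 control probe sets for 18S ribosomal RNA, and, with 2 spiked-in controls, compared between groups with two-sided exact permutation tests adjusted over 25 tests. The differences between successive steps of age were tested as contrasts in limma. For neighbouring genes, medians over windows of 25 measured genes in chromosome order were computed in single 16-week and 20-week glands as the difference from the mean of the other 16-week glands, less the median difference over all genes. In groups of 4 or 5 glands, a gland far from the others was sought with Dixon's test on list means and named genes. Each count was set against other splits of the same arrays, 100 per comparison.

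The gene test was tested on simulated data with the spread of these arrays. Planted changes of 1 on the log2 scale were recovered in 81% to 89% of genes, changes of 2 in 97% to 99%, and 3.59% to 6.77% of the calls had not been planted. A list shifted by 0.5 was found in 5 of 5 simulations, with 0 other lists called by camera. The simulated genes varied independently, whereas the estimated correlation between genes was 0.848 in the mitosis list and 0.658 in the replication list. Each gene had the same simulated spread in all groups, whereas the median SD was 0.153 in transgenic glands at 8 weeks and 0.247 at 20 weeks. The simulations therefore do not show how often camera calls an unshifted list of correlated genes. Nor do they show how the gene test performs with correlated genes or groups of unequal spread. Alternatives tried were normalization again across arrays by quantiles, medians or cyclic loess, the brighter 50% of genes, the mean of all probe sets of a gene, a fit of the compared groups alone, a robust variance trend, array weights, an adjusted p under 0.01, a minimum absolute log2 change of 1, leaving out glands 31 and 32, and leaving out each gland in turn. A covariate for 18S signal and an exact permutation test of list means were added after the data were seen.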

Results

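Gene expression was measured in 24 mouse mammary glands, 1 array each, on a log2 scale. The wild-type group held 5 glands at 8 weeks of age. The transgenic groups, whose mice express the SV40 large T antigen, a viral protein that binds p53 and the retinoblastoma protein, held 5 glands at 8, 12 and 16 weeks each and 4 glands at 20 weeks. Transgenic glands are called tumor in their titles at every age, including 8 weeks. Values covered 18194 genes. The labels name progression from the wild-type to the late transgenic gland as the subject, and the comparisons follow that order of ages. No older wild-type glands were measured, so changes with age in transgenic glands cannot be told from those of normal maturation. Hoxa1, the gene in the series title, had no probe set among those naming 1 gene and was not analysed here.

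The 20-week glands stood apart from all others. The first principal component held 58.8% of the variance, and glands 22, 23, 24 and 31 of the 20-week group scored 77.7, 81.4, 127 and 113 on it, against at most 8.29 for any other gland. The second component held 8.26%, and wild-type gland 36 had the highest score on it, 56.9. Correlations across genes, which are not independent replicates, lay between 0.966 and 0.976 within the 20-week group and had a median of 0.93 between that group and the rest. Within each other group they were at least 0.973. The control signal of 18S ribosomal RNA, a sign of RNA make-up, was 12.5 ± 0.13 (SD, n = 5) in wild-type glands, 11.7 ± 0.53 (n = 5) in transgenic glands at 8 weeks and 12.8 ± 0.22 (n = 4) at 20 weeks. These differences had an exact permutation p of 0.0318 for genotype and 0.0238 for 20 against 8 weeks, and both had an adjusted p of 0.198. The spiked-in controls Dap and Cre differed by -0.816 and 0.127 between 20 and 8 weeks (exact permutation p = 0.0238 and 0.0397, adjusted p = 0.198 each). In the other comparisons the spiked-in controls had adjusted p values of at least 0.51 in this test. The 3-prime to 5-prime differences of Actb and Gapdh moved by -0.0479 to 0.0586 between groups, with exact permutation tests giving adjusted p values of at least 0.966.

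**Figure D1:**
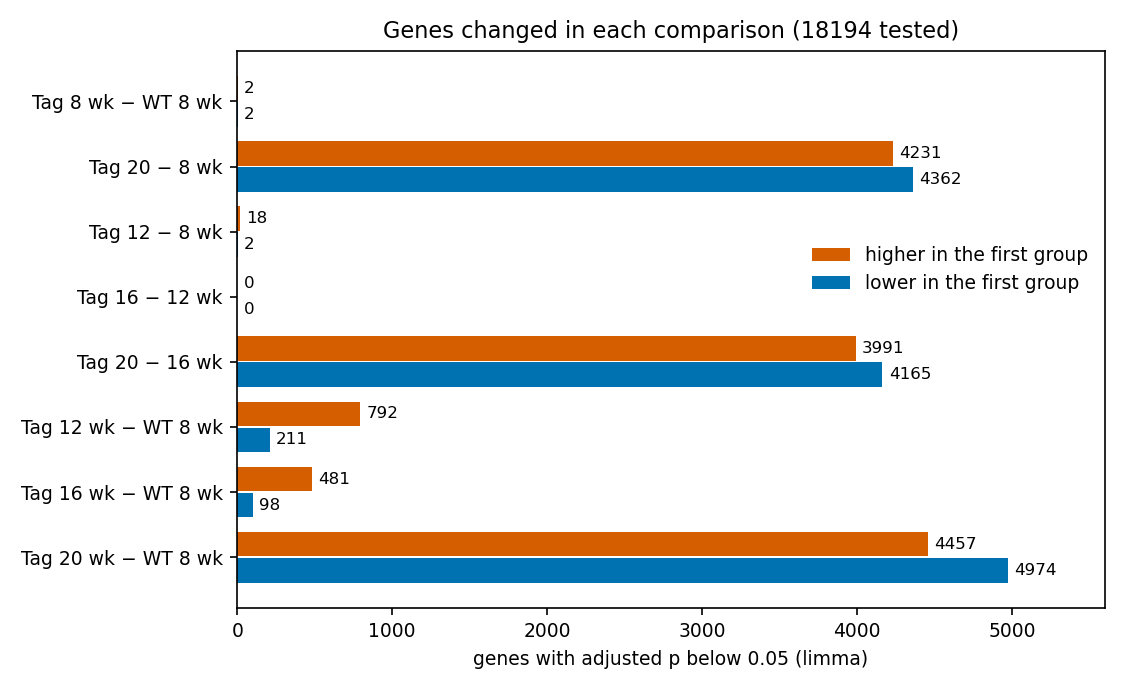
Number of genes with an adjusted p under 0.05 in limma (x axis, genes) for each comparison (y axis), split into genes higher and lower in the first group. The comparisons with 20-week glands called between 8156 and 9431 genes, and that of 16 with 12 weeks called 0.

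At 8 weeks, transgenic glands differed from wild-type glands in 4 of 18194 genes. The labels of these 8-week groups differ in genotype and in the word tumor, which the titles and tissue fields of the transgenic glands carry. Foxc1, which encodes a forkhead transcription factor, was 6.72 ± 0.15 (SD, n = 5) in transgenic and 5.31 ± 0.43 (n = 5) in wild-type glands, a log2 difference of 1.41 (SE 0.22, limma adjusted p = 0.014). Stard4, a sterol transfer protein, was higher by 1.00 (SE 0.15, adjusted p = 0.014). Slc2a3, a glucose transporter, fell by 1.25 with the transgene (SE 0.21, adjusted p = 0.0336). The remaining gene, the unnamed transcript A930001A20Rik, differed by -0.52 (adjusted p = 0.0336). With array weights limma called 408 genes, 221 of them higher, and with only the groups compared 0. The 2 groups did not overlap for these 4 genes, nor for 529 genes in total (2.91%, against 0.794% by chance). The calls of Foxc1, Stard4, Slc2a3 and A930001A20Rik ended with 18S signal as a covariate, chosen after the data were seen, with differences of 1.52, 0.97, -1.30 and -0.52 and adjusted p values of 0.185, 0.362, 0.362 and 0.37. With all probe sets averaged, Slc2a3 differed by -0.60 and Foxc1 by 1.20, and neither was called (adjusted p = 0.158 and 0.0739). The count of 4 genes was 8 without wild-type gland 33 and 7 without transgenic gland 1, but 2 without wild-type gland 37, 1 without 35, 36 or 2 and 0 without 3, 4 or 5. The calls also ended without wild-type gland 35 or 36 or transgenic glands 2, 3, 4 or 5 for Foxc1, without 35, 3, 4 or 5 for Stard4, with adjusted p values up to 0.0804 and 0.061. They ended without 34, 36, 37, 1, 2, 3, 4 or 5 for Slc2a3 and without 35, 36, 37, 1, 2, 3, 4 or 5 for A930001A20Rik, up to 0.137 and 0.152.

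**Figure D2:**
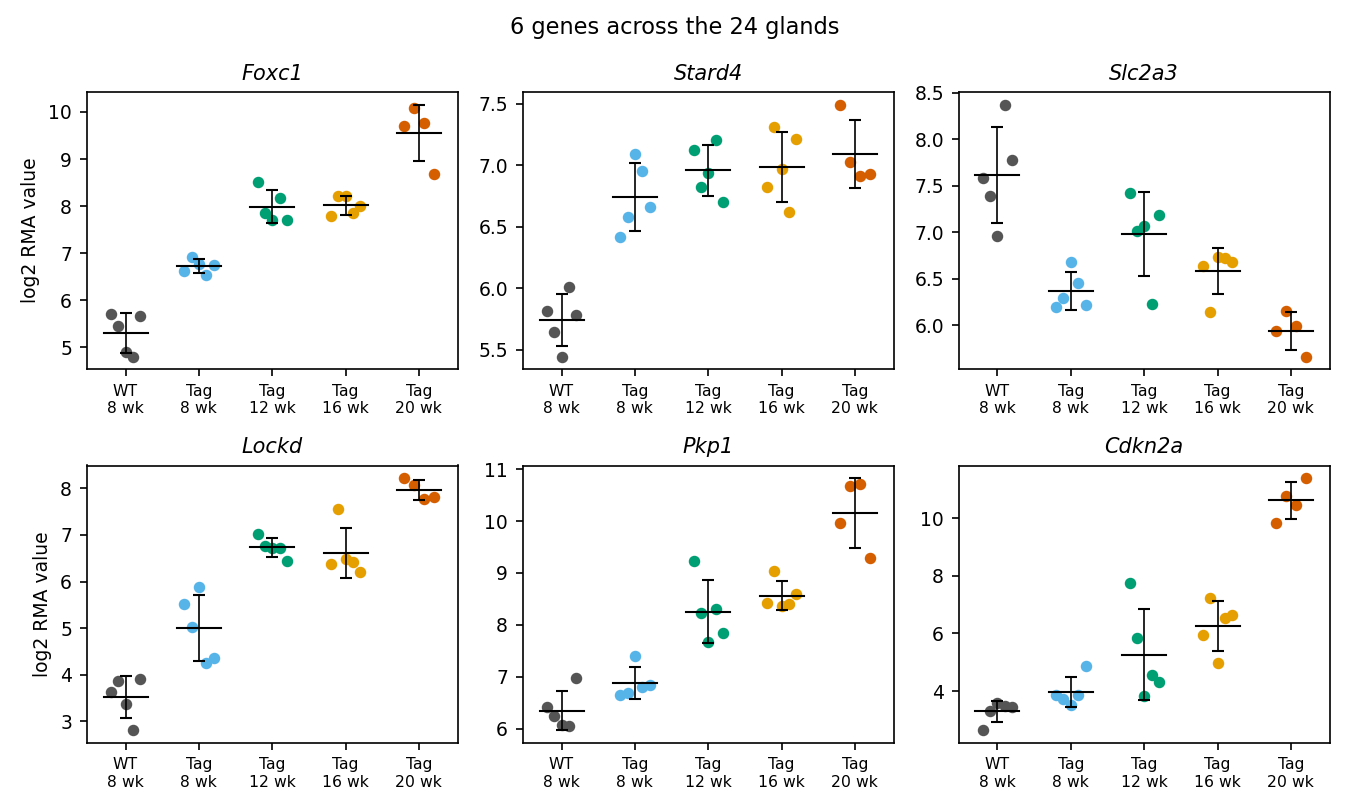
Log2 RMA value (y axis) of 6 genes in each gland (points) by group (x axis), with the mean and SD of the group. Foxc1 had group means of 5.31 in wild-type glands and 6.72, 7.99, 8.02 and 9.56 in transgenic glands at 8, 12, 16 and 20 weeks.

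Cell cycle genes lay higher in transgenic glands at 8 weeks as sets, although no single member passed the test over all genes. The DNA replication and E2F target list had a median difference of 0.55 over 36 genes (camera adjusted p = 6.51e-15), with Mcm5, a subunit of the replicative helicase, at 1.24 and Mcm6 at 1.18. This call was lost with an estimated correlation (adjusted p = 0.473 with an estimated correlation). The mitosis list had a median of 0.57 over 38 genes (adjusted p = 1.73e-09, adjusted p = 0.73 with an estimated correlation), with the proliferation marker Mki67 at 1.05. The list of homologous recombination and replication checkpoint genes had a median of 0.55 over 20 genes (adjusted p = 6.57e-12, adjusted p = 0.413 with an estimated correlation), with the nuclease gene Exo1 at 1.32. Adjusted over the list alone, 0 replication, 0 mitosis and 7 recombination genes passed limma's test. Camera also called lists of cell types and metabolism beside these. White adipocyte genes had a median of 0.27 (adjusted p = 0.00309, adjusted p = 0.746 with an estimated correlation), epithelial genes 0.19 (0.00423, adjusted p = 0.73 with an estimated correlation), glycolysis and hypoxia genes 0.13 (0.00511, adjusted p = 0.66 with an estimated correlation) and fibroblast genes -0.19 (0.0157, adjusted p = 0.743 with an estimated correlation). The epithelial call ended without gland 35 or 2 (adjusted p up to 0.0741) and the fibroblast call without 33, 34 or 2 (up to 0.0907). Without gland 2 these 2 medians were 0.10 and -0.10, and the glycolysis median was 0.21 without gland 35 or 37. With the 18S covariate the fibroblast call ended (adjusted p = 0.144) and the glycolysis median was 0.27. In total camera called 7 of 27 lists, 6 higher and 1 lower, whereas 0 were called with an estimated correlation, by fry or by the exact permutation test of list means. The mitosis list mean was 5.32 and 5.18 in wild-type glands 35 and 36, against 7.05, 7.10 and 7.09 in glands 33, 34 and 37. Without transgenic gland 2 the medians of replication and mitosis were 0.31 and 0.34, and without wild-type gland 35 or 36 that of mitosis was 0.30 or 0.31.

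Between 8 and 12 weeks, 18 genes rose and 2 fell in transgenic glands. Foxc1 rose by 1.27 (SE 0.22, limma adjusted p = 0.0226), from 6.72 ± 0.15 to 7.99 ± 0.35 (SD, n = 5 and 5). Pkp1, a protein of desmosomal plaques, rose by 1.38 (adjusted p = 0.0469), and the noncoding transcript Lockd rose by 1.73 (adjusted p = 0.0218). Bnipl rose by 1.27 and Ano9 by 1.18. Trpv1, a channel opened by heat and capsaicin, fell by 1.02 (adjusted p = 0.0218), and Coa8, an assembly factor of cytochrome c oxidase, fell by 0.43 (adjusted p = 0.0469). Groups did not overlap for 701 genes (3.85%, against 0.794% by chance). With array weights limma called 1431 genes, 747 of them higher, and with only the groups compared 2. The count of 20 genes rested on single glands, since it was 257 without transgenic gland 2 and 66 without gland 10 but 0 without gland 5, 6 or 9. It was 1 without gland 3, 2 without gland 4, 3 without gland 1 and 8 without gland 7. All 7 named genes lost their calls without gland 5, 6 or 9, all but Lockd without gland 3 and all but Trpv1 without gland 4, with adjusted p values up to 0.2. Pkp1, Bnipl, Foxc1, Ano9 and Coa8 also lost theirs without gland 1, and Pkp1, Ano9 and Coa8 without gland 7. Pkp1, Bnipl, Ano9 and Coa8 were not called with arrays centred on their medians (adjusted p = 0.0668, 0.0556, 0.0606 and 0.0556) or with the 18S covariate (0.0939, 0.0671, 0.0671 and 0.0857). With all probe sets averaged, Pkp1 (adjusted p = 0.0676) and Coa8 (-0.13, adjusted p = 0.577) were not called, nor was Coa8 after cyclic loess (adjusted p = 0.0587).

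The proliferation lists moved further up between 8 and 12 weeks. Adjusted over the list alone, 36 of 38 mitosis genes rose, with Ccna2, which encodes cyclin A2, at 1.46 and the kinetochore gene Cenpf at 1.42. The same count was 33 of 36 for replication, with Uhrf1, a maintenance factor of DNA methylation, at 1.34, and 17 of 20 for recombination, with Clspn at 1.27 and Brca1 at 1.22. Adjusted over all genes, 0 members of any list passed in limma. The medians were 1.12 for mitosis (camera adjusted p = 1.45e-28, adjusted p = 0.413 with an estimated correlation) and 0.87 for replication (5.19e-30, adjusted p = 0.306 with an estimated correlation). Recombination had a median of 0.75 (1.36e-18, adjusted p = 0.306 with an estimated correlation). The list of epithelial genes had a median of 0.58, and 14 of its 20 genes rose when adjusted over the list alone, among them Ehf (1.00), an epithelial transcription factor, and the tight junction gene Cldn4 (0.87). Its camera adjusted p was 1.85e-15, and adjusted p = 0.264 with an estimated correlation. White adipocyte genes had a median of -0.45 (camera adjusted p = 0.000111, adjusted p = 0.73 with an estimated correlation), with the glycerol channel gene Aqp7 at -1.09. Macrophage genes had a median of 0.29 (camera adjusted p = 4.12e-07, adjusted p = 0.473 with an estimated correlation), with 2 of 19 higher when adjusted over the list alone. Endothelial genes had a median of -0.23 (adjusted p = 0.00655, adjusted p = 0.73 with an estimated correlation), a call that ended without gland 4 or 6 (adjusted p up to 0.0924). Alveolar and milk genes had a median of 0.30 (adjusted p = 0.0345, adjusted p = 0.745 with an estimated correlation), with the milk protein genes Glycam1 at 3.20 and Wap at 2.70, but the call ended without gland 1, 2, 6, 7 or 8 (adjusted p up to 0.296). That median was 0.15 without gland 6, 0.14 without gland 7 and 0.45 without gland 9. Interferon genes had a median of 0.26 (adjusted p = 0.0157, adjusted p = 0.8 with an estimated correlation), a call that ended without gland 2, 4 or 6 (adjusted p up to 0.212), with medians of 0.10 without gland 6 and 0.41 without gland 1. Hoxa genes had a median of -0.17 (adjusted p = 0.0189, adjusted p = 0.473 with an estimated correlation), with Hoxa7 at -0.34, a call that ended without gland 1 or 6 (adjusted p up to 0.111, median -0.10 without gland 6). Hoxb, Hoxc and Hoxd genes had a median of -0.08 (adjusted p = 0.0285, adjusted p = 0.597 with an estimated correlation), a call that ended without gland 4, 5, 6 or 9 (adjusted p up to 0.0846). That median was -0.05 without gland 4 and -0.13 without gland 10. Camera called 11 lists, fry called 4 (replication, mitosis, recombination and epithelial), the exact permutation test of list means called 2, white adipocyte and the end of chromosome 6, and 0 were called with an estimated correlation. Without gland 6 camera called 6 lists.

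Between 12 and 16 weeks, 0 genes passed limma's test, and 567 genes had an unadjusted p under 0.05. With array weights, and without 12-week gland 6, limma called 1 gene. Groups did not overlap for 101 genes (0.555%, against 0.794% by chance). The proliferation lists had small negative medians, -0.24 for mitosis (camera adjusted p = 1.6e-05, adjusted p = 0.743 with an estimated correlation), -0.20 for replication (adjusted p = 2.2e-05, adjusted p = 0.73 with an estimated correlation) and -0.21 for recombination (adjusted p = 8.65e-06, adjusted p = 0.67 with an estimated correlation). Macrophage genes had a median of -0.17 (7.1e-05, adjusted p = 0.66 with an estimated correlation), which was -0.04 and no longer called without gland 6 (adjusted p = 0.124), -0.09 without gland 9 and -0.10 without gland 14. Fibroblast genes had a median of -0.09 (0.00372, adjusted p = 0.73 with an estimated correlation), which was -0.17 without gland 6, -0.14 without gland 8 and -0.03 without gland 9, where it was not called (adjusted p = 0.193). Alveolar and milk genes had a median of -0.24 (0.00655, adjusted p = 0.73 with an estimated correlation), which was -0.52 without gland 9. Their call ended without gland 6, 7 or 32, where the medians were -0.09, -0.13 and -0.16 (adjusted p up to 0.395). Hoxb, Hoxc and Hoxd genes had a median of 0.12 (0.00754, adjusted p = 0.473 with an estimated correlation), with Hoxc5 at 0.55, a call that ended without gland 6 (adjusted p = 0.119). Camera called 7 lists, and 0 were called by fry, by exact permutation or with an estimated correlation. Without 12-week gland 6, camera called 3 lists, and the medians of mitosis, replication and recombination were -0.12, -0.09 and -0.13. The call of replication ended without gland 6 (adjusted p = 0.0827). For mitosis the median was -0.16 both without 12-week gland 9 and without 16-week gland 11.

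By 20 weeks, 8593 of 18194 genes (47.2%) differed from 8 weeks in transgenic glands, with 4231 higher and 4362 lower. Cdkn2a, which encodes the inhibitors p16Ink4a and Arf, rose by 6.65 (SE 0.57, limma adjusted p = 2.52e-09), from 3.97 ± 0.53 (SD, n = 5) to 10.61 ± 0.64 (n = 4). The transcription factor genes Lhx2, a LIM homeobox gene, and Sox11 rose, Lhx2 from 2.86 ± 0.16 to 7.36 ± 0.17 and Sox11 by 4.34. Prkg2, a kinase activated by cyclic GMP, rose by 4.51, Hbegf, a ligand of the epidermal growth factor receptor, by 4.11, and Lgals7, a galectin of stratified epithelia, by 4.08. Tnnt2, the cardiac form of troponin T, rose by 4.12, the serine protease gene Klk6 by 4.04, the acute phase gene Saa3 by 4.02 and Dynap by 5.37. Among the 10 largest falls were genes of fat metabolism and adipocytes, Ces1f (-6.09), Ces1d (-5.84), Thrsp (-5.71), Retn (-5.63), which encodes resistin, and Mrap (-5.61). Cyp2e1, a cytochrome P450, fell from 12.91 ± 0.32 to 6.92 ± 1.17, the acute phase gene Orm1 by 5.94, the amylase gene Amy1 by 5.67, the casein gene Csn1s2a by 5.58 and Tmem45b by 5.75. All 20 genes kept their calls with arrays centred on their medians, after cyclic loess, with all probe sets averaged, with the 18S covariate and without any single gland, although Mrap was at -2.88 with all its probe sets averaged. Levels near background, such as those of Cdkn2a and Lhx2 at 8 weeks and Ces1f at 20 weeks, leave the size and the order of these changes uncertain. Ces1f and Ces1d belong to a family of similar genes whose probes may not tell them apart. Groups did not overlap for 6509 genes (35.8%, against 1.59% by chance).

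Proliferation genes rose throughout by 20 weeks. All 36 replication and E2F target genes and all 38 mitosis genes rose against 8 weeks, as did 19 of 20 recombination genes, and the counts adjusted over the list alone were the same. In the replication list E2f8, a repressor in the E2F family, rose by 2.99, the origin licensing factor gene Cdc6 by 2.94 and Rrm2, a subunit of ribonucleotide reductase, by 2.87. In the mitosis list Anln, needed for cell division, rose by 3.29, Ect2 by 3.12 and the kinetochore gene Ndc80 by 3.11. In the recombination list Rad54b rose by 2.98, Brca1 by 2.87 and Exo1 by 2.72. The medians were 2.24, 2.63 and 1.85 (camera adjusted p = 8.34e-18, 1.37e-15 and 3.8e-11, adjusted p = 0.444, 0.597 and 0.444 with an estimated correlation). Targets of p53 did not move one way: 7 of 21 rose, including the cell cycle inhibitor gene Cdkn1a (1.97), the apoptosis gene Pmaip1 (1.90) and Perp (1.81), 6 fell, including Tigar (-1.36), and 8 did not pass. Their median was 0.01 (camera adjusted p = 0.863), and the counts adjusted over the list alone were 7 and 6.

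**Figure D3:**
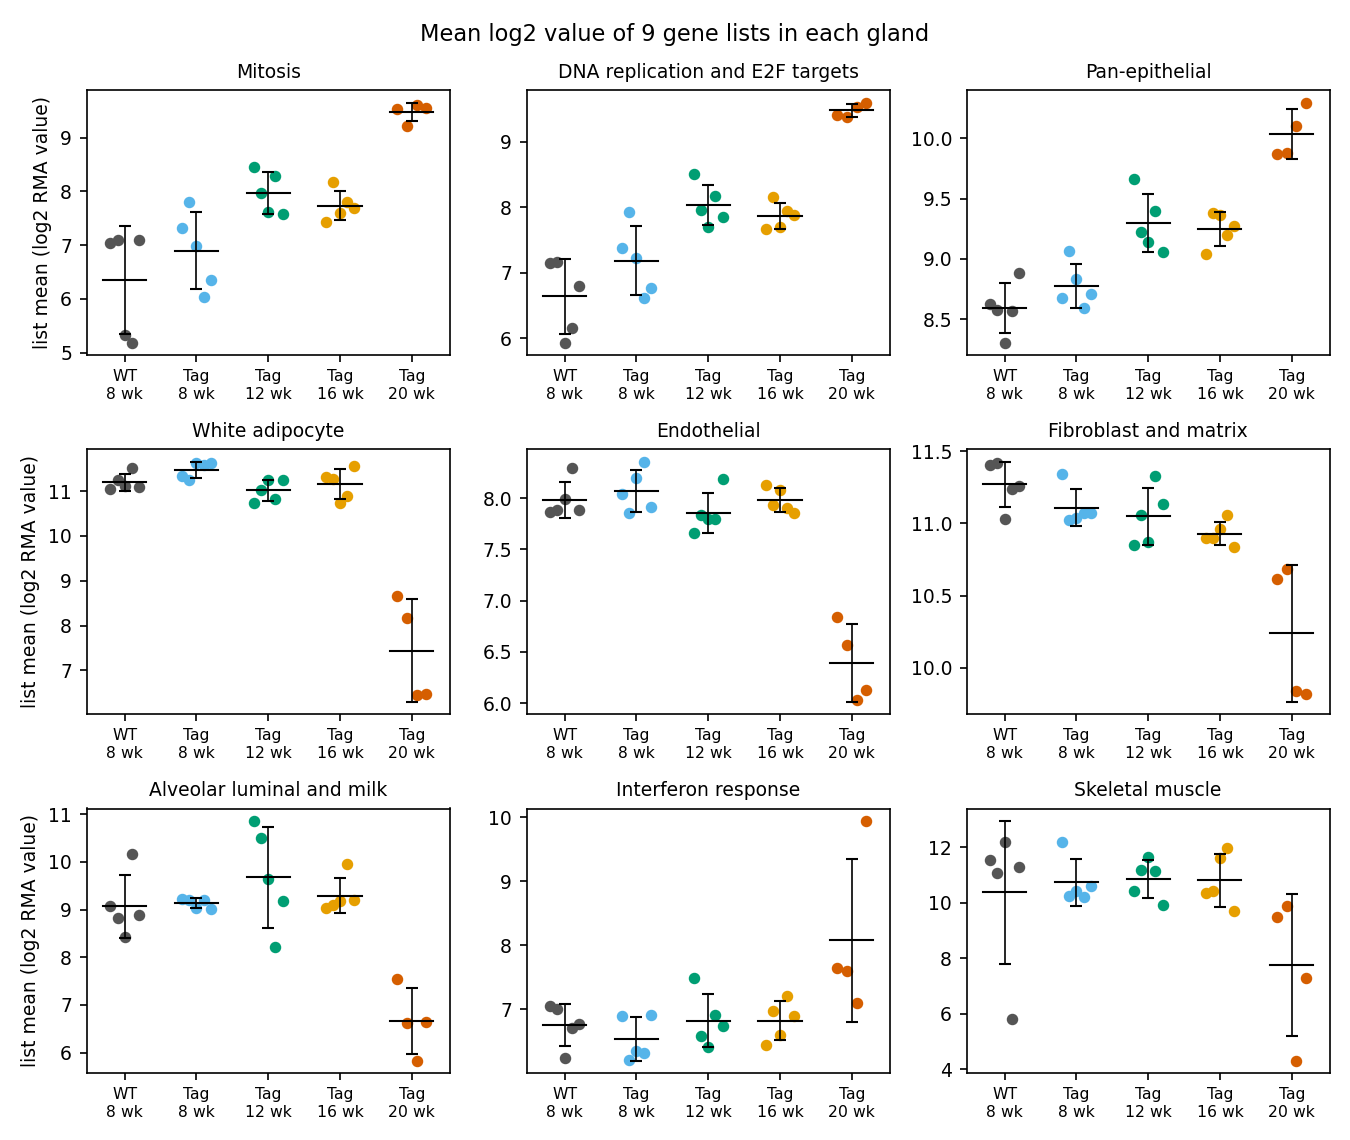
Mean log2 RMA value of the measured genes of 9 lists (y axis, a separate scale per panel) in each gland (points) by group (x axis), with the mean and SD of the group. The interferon panel shows 20-week gland 31 at 9.95 with the other 20-week glands between 7.10 and 7.65, and the skeletal muscle panel shows wild-type gland 36 at 5.82.

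Genes of adipocytes, vessels, stroma and muscle fell by 20 weeks. Each array measured a whole gland, so changed shares of cell types cannot be told from changes within cells, here and in the lists below. In the white adipocyte list 23 of 24 genes fell, with a median of -4.25 (camera adjusted p = 3.67e-16, adjusted p = 0.413 with an estimated correlation), among them leptin (Lep, -5.23) and the adipocyte regulator Pparg (-5.16). In the brown adipocyte list 7 of 10 fell, including Cox8b (-4.24) and the uncoupling protein Ucp1 (-3.79), with a median of -2.73 (adjusted p = 0.0285, adjusted p = 0.73 with an estimated correlation). That call was lost without gland 1, 24 or 31, with adjusted p values up to 0.0602. In the endothelial list 14 of 15 fell, with a median of -1.75 (2.2e-08, adjusted p = 0.413 with an estimated correlation), including the angiopoietin receptor Tek (-2.89), Sox17 (-2.84), the tight junction gene Cldn5 (-2.63) and von Willebrand factor (Vwf, -2.50). Of 19 fibroblast and matrix genes, 15 fell, including the proteoglycan genes Lum (-2.38) and Dcn (-2.10) and Dpt (-2.97), and 1 rose, the matrix gene Tnc (3.07). The median was -0.91 (0.00027, adjusted p = 0.72 with an estimated correlation). Adjusted over the list alone, 2 fibroblast genes rose, and the falls in these 4 lists were as many as over all genes. In the skeletal muscle list 20 of 25 fell (23 adjusted over the list alone), including the calcium store protein Casq1 (-3.71) and the troponin Tnnt3 (-3.63), with a median of -3.15 (0.00262, adjusted p = 0.761 with an estimated correlation). Without gland 24 that median was -1.91, and list means were 9.49, 9.90, 4.31 and 7.30 in glands 22, 23, 24 and 31.

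Epithelial genes moved in different directions by type. Of 20 genes shared by epithelia, 18 rose and 1 fell, with a median of 1.37 (camera adjusted p = 2.17e-08, adjusted p = 0.413 with an estimated correlation). The keratin gene Krt7 rose by 2.32, the claudin genes Cldn4 and Cldn7 by 2.10 and 1.99, and Epcam, an epithelial adhesion molecule, by 1.88, while the keratin gene Krt19 fell by 1.55. Of 12 genes of hormone-sensing luminal cells 7 fell and 0 rose, with a median of -0.84 (0.0013, adjusted p = 0.264 with an estimated correlation). Cited1 fell from 9.17 ± 0.09 (SD, n = 5) to 3.94 ± 0.21 (n = 4), Foxa1, a partner of the estrogen receptor, fell by 3.83, the progesterone receptor gene Pgr by 3.50 and Stc2 by 2.86. Of 19 alveolar and milk genes 11 fell and 1 rose, with a median of -2.12 (0.00156, adjusted p = 0.73 with an estimated correlation), including the milk protein genes Lalba (-5.49) and Csn1s1 (-4.99) and the milk fat globule gene Btn1a1 (-5.23). With 18S signal as a covariate this median was -3.30. Of 19 basal and myoepithelial genes 10 fell and 4 rose (11 and 5 adjusted over the list alone), and camera did not call the list (median -1.10, adjusted p = 0.0805), although fry did (adjusted p = 0.000794). Its mean was 7.90 in gland 23, against 7.61 for the 8-week group, and 6.33, 6.57 and 6.43 in glands 22, 24 and 31. The members that fell included genes of contraction, the oxytocin receptor Oxtr (-4.46), the smooth muscle myosin Myh11 (-3.54) and calponin (Cnn1, -2.97), whereas the basal keratin gene Krt14 rose by 1.78. Counts for the other lists were the same when adjusted over the list alone.

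Interferon response genes rose by 20 weeks, and immune cell genes split. Of 21 interferon genes 17 rose (18 adjusted over the list alone) and 0 fell, with a median of 1.59 (camera adjusted p = 4.32e-05, adjusted p = 0.73 with an estimated correlation). The chemokine gene Cxcl10 rose by 2.73, Oasl2 by 2.35 and Usp18, a regulator of interferon signalling, by 2.33. The list mean was 9.95 in gland 31 and between 7.10 and 7.65 in the other 20-week glands, and the median without gland 31 was 1.02. Of 19 macrophage genes 8 rose and 3 fell (adjusted p = 0.239), including the scavenger receptors Msr1 (1.17) and Cd163 (-1.62). Of 19 T and NK cell genes 2 rose and 8 fell (adjusted p = 0.275), including the killer cell genes Klrd1 (-1.50) and Gzma (-1.43). Of 18 B and plasma cell genes 3 rose and 3 fell (adjusted p = 0.902), including Jchain (-2.15), which joins immunoglobulins, and Blnk (1.57). These 3 immune cell lists had the same counts when adjusted over the list alone, and camera called none of them, while fry called the T and NK cell list (adjusted p = 0.0119).

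Other lists changed in part by 20 weeks, and camera called none of those in this paragraph for 20 against 8 weeks. Of 20 matrix proteases and their inhibitors 6 rose (7 adjusted over the list alone) and 6 fell, with the collagenase Mmp13 at 3.64, the inhibitor Timp1 at 2.81, Mmp12 at 2.04 and Adamts5 at -2.33 (adjusted p = 0.863). Of 12 mesenchymal transition genes 7 fell and 3 rose (4 adjusted over the list alone), with the transcription factors Zeb1 at -2.43 and Twist2 at -1.82 (adjusted p = 0.202). Of 23 glycolysis and hypoxia genes 8 rose and 4 fell, with the carbonic anhydrase Car9 at 3.27, Bnip3 at -2.56 and the hexokinase Hk2 at -2.25 (adjusted p = 0.239). Of 24 Hoxb, Hoxc and Hoxd genes 8 fell and 2 rose, with Hoxc8 at -3.10, Hoxc5 at -2.37 and Hoxd8 at -2.35 (adjusted p = 0.0507). Of 9 measured Hoxa genes 4 fell, including Hoxa5 (-0.93) and Hoxa7 (-0.90), and 0 rose (adjusted p = 0.158). Among markers of other tissues, 1 of 13 skin genes rose (Klk7, 0.69) and 1 fell (Krt10, -0.53), and 2 of 6 Schwann cell genes rose (Ncmap among them, 3.12) and 3 fell (Mbp among them, -3.31). Of 8 salivary genes Amy1 alone changed, and of 12 neuroendocrine genes 4 fell, including Scg3 (-1.96), and 0 rose. The adjusted p values of these 4 lists were 0.957, 0.872, 0.538 and 0.67. Other tests did call some lists of this paragraph. By the exact permutation test, the list means of the mesenchymal, Hoxa, Hoxb to Hoxd, salivary and neuroendocrine lists were lower (adjusted p = 0.0346 each). Yet the median differences of the salivary and neuroendocrine lists were -0.08 and 0.07, and 7 of 12 neuroendocrine genes had a higher mean at 20 weeks. Fry called the Hoxb to Hoxd (adjusted p = 2.78e-06), Hoxa (0.000335), mesenchymal (0.000378), salivary (0.0182) and glycolysis lists (0.0315).

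Genes near the end of chromosome 6, around the position of Kras, rose by 20 weeks in part of the glands. Of 26 measured genes of this list 17 rose and 3 fell, both also when adjusted over the list alone, with a median of 1.94 (camera adjusted p = 0.000824, adjusted p = 0.73 with an estimated correlation). C2cd5 rose by 3.59, the clock-related repressor Bhlhe41 by 3.31 and the Mediator subunit Med21 by 2.99, while Gys2, the liver form of glycogen synthase, fell by 4.58. Against the mean of the 16-week glands, the list median was 2.56 in gland 22, 2.66 in gland 24 and 3.37 in gland 31 but -0.08 in gland 23. Among 17539 windows of 25 neighbouring genes, the highest window median overlapping this stretch was 2.62, 2.93 and 3.44 in glands 22, 24 and 31, against 0.66, 1.02 and 1.33 for the highest window elsewhere. In 16-week gland 15, set against the other 16-week glands, the highest window also overlapped this stretch (0.46, against 0.25 elsewhere), with a list median of 0.31. In glands 24 and 31 Plekha5 stood at 4.03 and 3.95, whereas in gland 22 it was at -0.14 and Pyroxd1, further along, at 1.87. Not all genes of this end of the chromosome were higher: Abcc9 was at -1.46 and -2.01 in glands 24 and 31, and Slco1c1, a gene near the floor between Plekha5 and Pyroxd1, at 0.16 and 0.03. The last measured gene of the chromosome, Resf1, was at 3.76, 4.06 and 3.92 in glands 22, 24 and 31. Kras itself had no probe set among those naming 1 gene. By the exact permutation test of list means, with 4 glands against 5, the list was not called (adjusted p = 0.169).

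**Figure D4:**
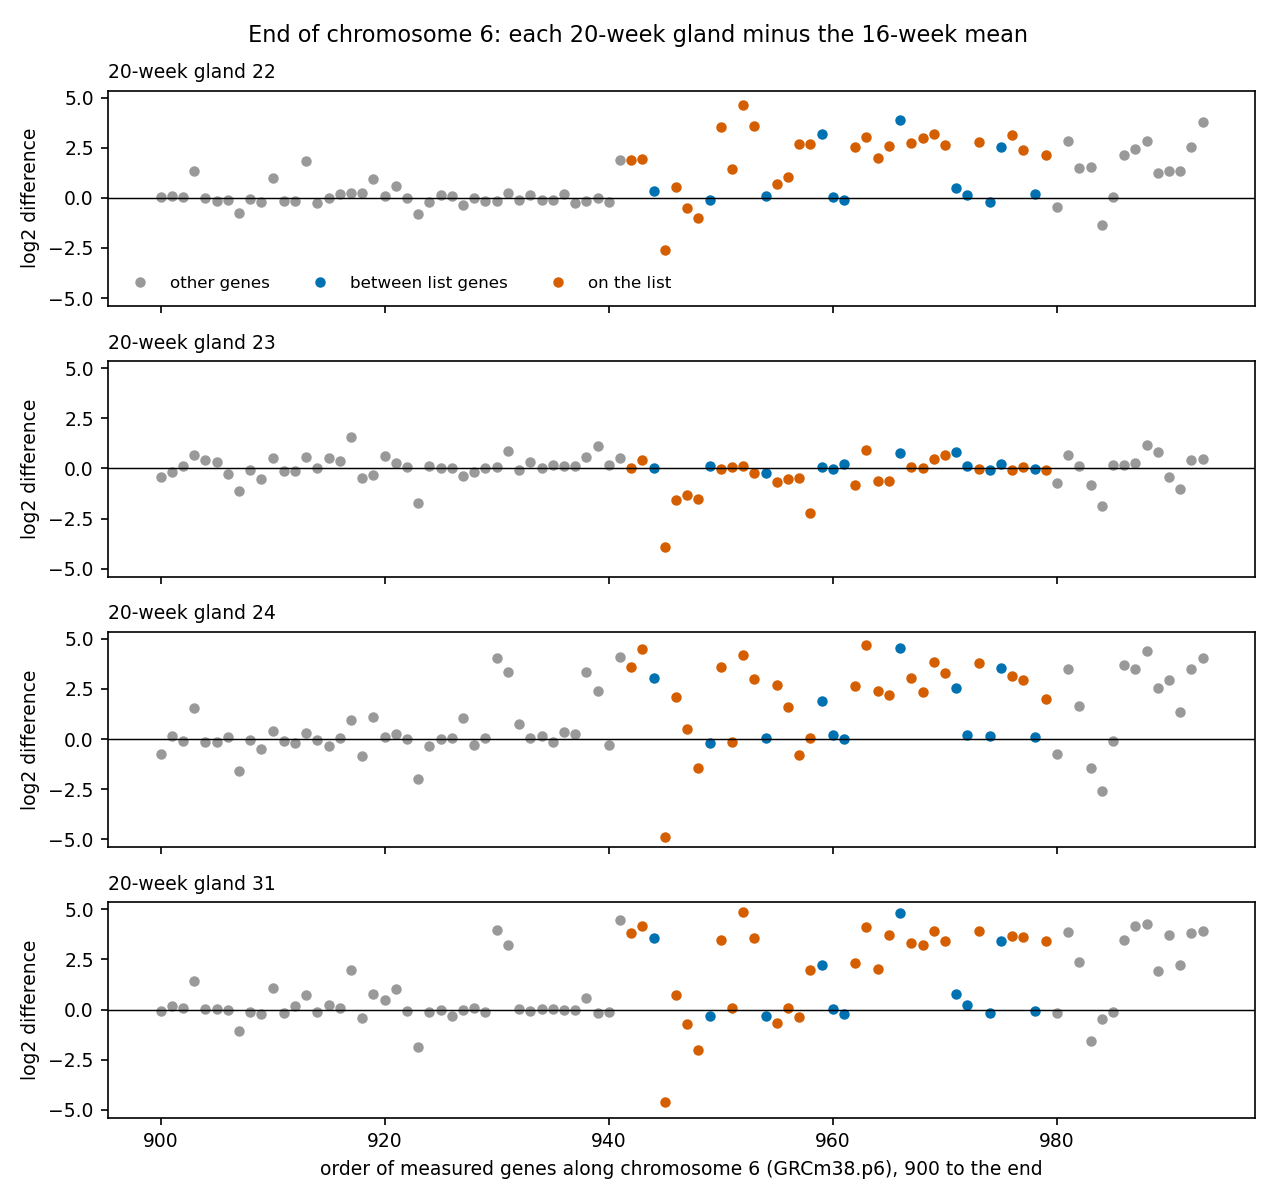
Log2 difference from the mean of the 16-week glands (y axis) for measured genes in their order along the end of chromosome 6 (x axis, order in GRCm38.p6), with 1 panel per 20-week gland and colours for genes on the list, between list genes and elsewhere. The list median was 2.56, 2.66 and 3.37 in glands 22, 24 and 31 and -0.08 in gland 23.

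Most of the change by 20 weeks lay in the last step of age. Between 16 and 20 weeks 3991 genes rose and 4165 fell (8156 of 18194, 44.8%), and groups did not overlap for 5331 genes (29.3%, against 1.59% by chance). Prkg2 rose by 4.89, Cdkn2a by 4.34, Edil3, a matrix protein that binds integrins, by 3.65, Lhx2 by 3.63 and Klk6 by 3.60. Ces1f fell by 5.58, Tmem45b by 5.47, Cyp2e1 by 5.44, Ces1d by 5.44 and leptin (Lep) from 9.28 ± 0.69 (SD, n = 5) to 3.88 ± 0.87 (n = 4). Edil3 rose by 1.10 when all its probe sets were averaged. The step from 16 to 20 weeks differed from that from 12 to 16 weeks in 4652 genes, tested as a difference of contrasts in limma. The step from 12 to 16 weeks differed from that from 8 to 12 weeks in 0 genes by limma, with 1279 at an unadjusted p under 0.05.

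Between 16 and 20 weeks all 36 replication genes, all 38 mitosis genes and 19 of 20 recombination genes rose, with medians of 1.53, 1.75 and 1.41 and with Ccne2, which encodes cyclin E2, at 2.12, the spindle gene Tpx2 at 2.19 and Brip1 at 2.01. The counts adjusted over the list alone were equal, and adjusted p = 0.473, 0.684 and 0.473 with an estimated correlation. White adipocyte genes fell in 23 of 24 cases (median -3.73, adjusted p = 0.413 with an estimated correlation), and endothelial genes fell in 14 of 15 (median -1.58, adjusted p = 0.413 with an estimated correlation), with the same counts when adjusted over the list alone. Of the 20 epithelial genes 15 rose and 1 fell, Krt19 at -1.80 (17 and 1 adjusted over the list alone, median 0.98, adjusted p = 0.473 with an estimated correlation). Alveolar and milk genes fell in 11 of 19 cases (13 adjusted over the list alone, median -3.11, adjusted p = 0.662 with an estimated correlation). Of 21 interferon genes 14 rose, also when adjusted over the list alone, with a median of 1.34 that was 0.64 without gland 31 (adjusted p = 0.73 with an estimated correlation). Of 25 muscle genes 21 fell (24 adjusted over the list alone), with a median of -3.32 that was -1.97 without gland 24 (adjusted p = 0.746 with an estimated correlation). Of 12 hormone-sensing genes 7 fell, including Cited1 (-4.54), with a median of -0.79 (adjusted p = 0.00119, adjusted p = 0.264 with an estimated correlation), and of 19 fibroblast genes 12 fell and 2 rose, with a median of -0.65 (0.00188, adjusted p = 0.73 with an estimated correlation). Of 26 genes at the end of chromosome 6, 17 rose and 3 fell, with a median of 2.02 (6.41e-05, adjusted p = 0.73 with an estimated correlation). Of 10 brown adipocyte genes 7 fell, with a median of -2.60 (0.0269, adjusted p = 0.73 with an estimated correlation), a call that ended without gland 24 (adjusted p = 0.0553).

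The other lists called between 16 and 20 weeks were near the threshold. Of 19 basal genes 8 fell and 3 rose, with a median of -1.03 (camera adjusted p = 0.0433, adjusted p = 0.743 with an estimated correlation), a call that ended without gland 14, 22 or 31 (adjusted p up to 0.176). With all probe sets averaged that median was -0.38 (adjusted p = 0.0718), and with the 18S covariate the call also ended (adjusted p = 0.0651). Of 23 glycolysis and hypoxia genes 10 rose, including Car9 (3.05), and 4 fell, including Bnip3 (-2.45), with a median of 0.45 (0.0351, adjusted p = 0.73 with an estimated correlation). This call ended without gland 13 or 22 (adjusted p up to 0.176), with arrays centred on their medians (adjusted p = 0.0602) and with the 18S covariate (adjusted p = 0.132). Without glands 31 and 32 the call was kept, with a median of 0.71 (camera adjusted p = 0.00513). Of 24 Hoxb, Hoxc and Hoxd genes 9 fell, including Hoxc8 (-2.54), and 2 rose, with a median of -0.10 (0.0351, adjusted p = 0.619 with an estimated correlation). That call ended without gland 22 or 31 (adjusted p up to 0.0665) and after cyclic loess (adjusted p = 0.0646), and the median was -0.16 without gland 13 or 24, -0.20 without gland 23 and -0.05 with arrays centred on their medians. Counts of the 7 lists from hormone-sensing to these were the same when adjusted over the list alone. The 18S control signal was higher by 0.845 at 20 than at 16 weeks (exact permutation p = 0.0397, adjusted p = 0.198). Camera called 16 lists, 7 up and 9 down, fry 21 and exact permutation 13, which did not include interferon or muscle (adjusted p = 0.0564 each), glycolysis (0.134), the end of chromosome 6 (0.162) or basal genes (0.169), but 0 were called with an estimated correlation.

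Later transgenic glands were also compared with wild-type glands, which exist at 8 weeks alone, so that genotype and age differ together. The plan for these comparisons named gene counts and Hoxa1 alone, and the values for gene lists given here were added to it. At 12 weeks 1003 genes differed, 792 higher and 211 lower, at 16 weeks 579 (481 and 98), and at 20 weeks 9431 (4457 and 4974). At 12, 16 and 20 weeks, 32, 26 and 36 of 36 replication genes were higher than in wild-type glands, with medians of 1.38, 1.20 and 2.81. For mitosis genes these counts were 30, 19 and 38 of 38, with medians of 1.61, 1.38 and 3.10. Recombination genes were higher in 19, 14 and 20 of 20 cases, and epithelial genes in 12, 11 and 19 of 20. White adipocyte genes were lower in 0, 0 and 24 of 24 cases, with medians of -0.05, -0.03 and -3.66. The counts at 12 and 16 weeks depended on single glands, being 633 without gland 9 and 641 without gland 6 for 12 weeks, and 313 without gland 13 and 371 without wild-type gland 35 for 16 weeks. With array weights they were 2608 and 1220, and with the 18S covariate 645 and 345.

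Across the 19 transgenic glands, 7131 genes had a slope with age, 3506 of them rising and 3625 falling, whereas 2757 had one with the 18S covariate and 3968 with array weights. The successive steps called 20 genes for 12 against 8 weeks, 0 for 16 against 12 and 8156 for 20 against 16 weeks. No slope was fitted without the 20-week glands, so the count of slopes does not show a steady change with age. Cdkn2a had group means of 3.97, 5.26, 6.27 and 10.61 at 8, 12, 16 and 20 weeks, against 3.29 in wild-type glands, and Pkp1 had 6.88, 8.25, 8.56 and 10.16, against 6.35. A slope of at least 1 per 4 weeks in either direction was found for 162 genes, 24 rising and 138 falling. Foxc1 and Lockd had their highest group means at 20 weeks, 9.56 and 7.97.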

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

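The tests of gland 23 for composition, of expressed genes from the first chromosome 6 list gene to the chromosome end, of gland 31 for a processing set and for lymphocytes, and of muscle loss with the 20-week stage alone were chosen, and their bounds set, after the results were seen. The other tests in this part were written before. By their bounds, the loess value counted against the deposited normalization, the off-list median against a gain of the region, and the muscle share for muscle tissue. The limits given below for these tests were not part of those bounds.

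Single glands lay far from the rest of their group by Dixon's test in 12 of 135 tests of list means and 6 of 71 tests of named genes, where chance gives about 1 in 20 groups. In wild-type glands, gland 36 was low for the skeletal muscle list (5.818, others 11.07 to 12.18) and for brown adipocyte genes such as Ucp1 (5.95, others 8.195 to 8.528), and gland 37 was low for the Hoxa list (4.4, others 4.511 to 4.536). At 8 weeks transgenic gland 1 was high for skeletal muscle (12.21, others 10.19 to 10.61) and fibroblast genes (11.34, others 11.02 to 11.08). Gland 5 was high for the end of chromosome 6 (7.761, others 7.538 to 7.573), Cdkn2a (4.874, others 3.513 to 3.875) and Prkg2 (7.641, others 5.591 to 6.105). Pkp1 was high in gland 3 (7.397, others 6.65 to 6.846) and Cyp2e1 low in gland 4 (12.37, others 12.95 to 13.16). At 16 weeks gland 13 was high for recombination genes (6.85, others 6.472 to 6.523), gland 14 low for B and plasma cell genes (4.347, others 4.673 to 4.725), and gland 15 high for alveolar and milk genes (9.949, others 9.033 to 9.209) and Prkg2 (7.551, others 4.94 to 5.682). At 20 weeks gland 23 was low for the end of chromosome 6 (7.11, others 9.496 to 9.625) and high for basal genes (7.897, others 6.325 to 6.567) and for the Hoxb, Hoxc and Hoxd list (4.438, others 4.316 to 4.33), and Hbegf was low in gland 31 (9.193, others 9.885 to 9.934).

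The change from 16 to 20 weeks differed from that from 12 to 16 weeks in 4652 genes, by a test of the difference in limma. Among 10093 probe sets that name no single gene, which the report does not use, 2784 (27.6%) changed from 8 to 20 weeks, 1804 of them higher and 980 lower.

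The end of chromosome 6, with C2cd5 and Med21, was high in 20-week glands 22, 24 and 31 but not in gland 23. The list median was 1.86 after cyclic loess, against 1.94 as deposited. Cyclic loess started from values that the authors had already normalized, so it cannot undo that step. However, RMA normalizes by signal level and does not use gene position. The highest window medians overlapping this stretch were 2.617, 2.927 and 3.437 in glands 22, 24 and 31, against 0.664, 1.024 and 1.335 elsewhere. These values argue against the deposited normalization as the source of the rise in these glands. A tissue composition shared by the 20-week glands stays open, since the list median of -0.076 in gland 23 (quartiles -0.657 to 0.0679) is that of 1 gland and part of the pattern itself. A gain of the region in single glands stays open too: the lowest median of the 11 genes off the list inside the stretch (without Arntl2, another name of the list entry Bmal2) was 0.038, but their median level at 16 weeks was 3.06, against 6.46 for the median gene, so most were too dim for the bound set for this test. Among 10 off-list genes expressed at 16 weeks, from the first list gene to the chromosome end and all but Ints13 beyond the last list gene, the medians were 2.325, 3.507 and 3.769 in glands 22, 24 and 31 and 0.289 in gland 23, so a gain may explain the pattern, as a hypothesis found and tested on the same data without DNA.

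Interferon genes such as Cxcl10 were high in gland 31 (list mean 9.948, others 7.104 to 7.652). A processing set shared by glands 31 and 32, which have adjacent gland numbers, stays open: gland 32 differed from the other 16-week glands by 0.0962, but this is 1 gland. More T, NK and B cells in gland 31 stay open: the T and NK cell list differed by 0.102 and the B and plasma cell list by -0.0429, but both lists lay near the floor (gland 31 at 4.712 and 4.256, median gene 6.3). No other biological explanation was tested.

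Skeletal muscle genes such as Casq1 and Tnnt3 varied between glands within groups. The 25 genes moved together, with 95% of their variance on 1 component and all 25 in the same direction, against a median of 64.4% and at most 82.6% in 100 random lists of 25 genes. Muscle tissue in varying amount in the samples stays open, since lists of jointly regulated genes reached similar shares (mitosis 95.8%, white adipocyte 94.6%) and the share does not tell the 2 apart. For loss with the 20-week stage alone, the list varied more between glands than each other list in 3 of the 4 earlier groups. This measure replaced a comparison with wild-type gland 36 that had decided nothing. In 2 of these groups the first rank rests on wild-type gland 36 and transgenic gland 1, without which the list ranked 3 and 9 among the 27 lists. The list thus varied before 20 weeks too, but the measure restates the pattern itself. It does not decide how much of the fall belongs to the 20-week stage, which stays open.

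Other splits of the same arrays into groups of the same sizes tested whether chance can be excluded, with 100 splits per comparison, the real one included. For 8-week transgenic against wild-type glands, where Foxc1 was called, 3 splits gave as many genes as the real 4, which is under the bound of 0.05. The others among them mixed the genotypes and gave 87 and 110 genes, for reasons that were not tested. The real count was also 0 with only the groups compared and 0 with the 18S covariate, so chance is not taken as excluded for it. The real split alone gave as many genes for 20 against 8 weeks (8593, highest other 6571), 12 against 8 weeks (20, highest other 1) and 20 against 16 weeks (8156, highest other 5721). The same held for 12, 16 and 20 weeks against wild type (1003, 579 and 9431, highest others 2, 11 and 7670) and for the age slope (7131, highest other order of ages 1). These shares were under the bound of 0.05, with glands treated as independent. The count for 12 against 8 weeks was 2 with only the groups compared and 0 without gland 5, 6 or 9. Chance is therefore not taken as excluded for that count either. For 16 against 12 weeks the real count was 0 genes by limma (567 at an unadjusted p under 0.05), so all 100 splits had to give as many, and they say nothing about chance (highest other 1).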

How the results depend on the processing

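The 18S covariate and the exact permutation of list means were tests chosen after the data were seen. No alternative could be run for Hoxa1, which had no probe set among those naming 1 gene. No result reversed. Of the single genes and lists, 1248 comparisons with an alternative gave the same direction and side of the threshold, and 239 kept the direction but no longer passed; of the counts, 225 stayed within 1.5 times the main count and 66 moved. Alternatives of normalization, probe set choice and array weighting are described with the processing. An adjusted p under 0.01 or a change of at least 1 lowers counts by construction; for the other alternatives the cause was not tested. For genes of 8-week transgenic against wild-type glands (4, Foxc1 among them), the count was 0 with only the groups compared, 408 with array weights, 0 at an adjusted p under 0.01, 2 without glands 31 and 32, 0 with 18S signal as covariate, and 0 to 8 leaving out single glands (0 without 3, 4 or 5 and 8 without 33). For 12 against 8 weeks (20) it was 6 with arrays centred on their medians, 11 in the brighter 50% of genes, 11 with the mean of all probe sets, 2 with only the groups compared, 1431 with array weights, 0 at an adjusted p under 0.01, 10 at a change of at least 1, 11 without glands 31 and 32, 7 with 18S, and 0 to 257 leaving out single glands (0 without 5, 6 or 9 and 257 without 2). For 16 against 12 weeks (0 by limma, 567 at an unadjusted p under 0.05) it was 1 with array weights and 0 to 1 leaving out single glands (1 without 6). For 20 weeks a change of at least 1 gave 3346 against 8 weeks, 2760 against 16 weeks and 3579 against wild type. For 12 weeks against wild type (1003) the count was 2608 with array weights, 462 at an adjusted p under 0.01, 311 at a change of at least 1, 645 with 18S and 633 to 972 leaving out single glands (633 without 9 and 641 without 6). For 16 weeks against wild type (579) it was 1220 with array weights, 218 at an adjusted p under 0.01, 218 at a change of at least 1, 345 with 18S and 313 to 554 leaving out single glands (313 without 13 and 371 without 35). For the age slope (7131) it was 3968 with array weights, 162 at a slope of at least 1 and 2757 with 18S. Leaving out single glands gave 7936 to 8713 genes for 20 against 8 weeks and 7266 to 8351 for 20 against 16 weeks. With an estimated correlation camera called 0 lists in each of the 5 comparisons. Fry called 0, 20, 4 and 0 lists for 8-week genotype, 20 against 8, 12 against 8 and 16 against 12 weeks, where camera called 7, 13, 11 and 7, and exact permutation called 0 for genotype, 2 for 12 against 8, 0 for 16 against 12, 16 for 20 against 8 and 13 for 20 against 16 weeks, where camera called 16. Leaving out single glands gave 6 to 12 lists for 12 against 8 weeks and 3 to 9 for 16 against 12 weeks (6 and 3 without gland 6). With 4 or 5 glands per group, single glands limit the small counts, and signal near the array background limits dim genes.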
